A study of Mus musculus with 2 samples.

How the data were processed

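MicroRNA libraries of 2 biological replicates of C2C12 myocytes, differentiated for 72 h, were analysed. Per the labels, they were made from total RNA of mouse cells with a microRNA sequencing protocol that keeps short RNA, and adapters were trimmed from the reads. Each library was deposited as a table of read counts per microRNA gene. Per the deposited notes, the genome build was mm10 and the annotation GENCODE M21. The aligner, the counting program and their versions are not given in the sources used here. The deposited counts are whole numbers and were not normalized by the authors as far as the values show. Each table has 3 count columns (either strand, the gene's own strand, the opposite strand) and 4 further entries for unmapped, multi-mapped, unassigned and ambiguous reads. This layout is that of the STAR aligner's gene count table, in which only uniquely mapped reads are given to genes. The counts were therefore read as counts of uniquely mapped reads, with reads that fit more than 1 place held in the multi-mapped entry. Nothing in the files separates the 5p and 3p arms of a hairpin.

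In each table the genes and the 4 entries added up to the same total in all 3 columns: 15349205 reads in replicate 1 and 18450359 in replicate 2. Of these, 22.0% and 17.9% were multi-mapped, 22.7% and 23.1% unmapped, and 5.88% and 5.57% mapped uniquely but to the sense strand of no microRNA gene. The 4 entries were left out of library sizes and tests. The sense-strand column was used throughout. In the either-strand column, reads of genes that overlap on opposite strands are ambiguous (4.83% of reads in replicate 1 and 8.05% in replicate 2), and 9 genes with a mean of at least 100 CPM, Mir378a among them, have no counts there. All 2202 gene identifiers matched the M21 annotation, from which symbols, coordinates (1-based, mm10), host genes and hairpin sequences were taken. A symbol that belongs to more than 1 identifier occurred 1 time and was kept as separate genes.

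CPM, counts scaled to a library total of 1000000, were computed here from the deposited counts over the sense-strand counts assigned to microRNA genes (7581366 and 9865298). A gene was called detected with at least 10 counts in each library. Values are means ± SD of n = 2 replicates. In these libraries 3 counts, the one-sided 95% limit that a count of 0 allows, equal 0.396 and 0.304 CPM. The libraries carry no molecular identifiers, so PCR copies are not independent molecules. The binomial and chi-square tests and the limits for a count of 0 cover counting error only. Bootstrap intervals and permutation tests were taken over genes or clusters and do not measure the spread between cultures.

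Pearson and Spearman correlations were taken over log2(CPM + 1) of detected genes, with an interval from 1000 bootstraps over genes. The common dispersion was estimated with edgeR from TMM-scaled counts and an intercept-only design, and its square root was given as the biological coefficient of variation, with 100 bootstraps over genes. Each detected gene's counts were compared between the libraries with an exact two-sided binomial test given the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. A chi-square test of the counts checked that the libraries were not the same library counted again. With 1 group, no test between conditions was possible.

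The 12 lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, except where a test is said to have been chosen later. The lists were muscle-enriched microRNAs, widely expressed microRNAs tied to myoblast differentiation, microRNAs of proliferating myoblasts, the miR-17-92 clusters, the let-7 family, the Dlk1-Dio3 cluster, and mesenchymal, epithelial, blood, neural, pluripotent, and liver and endothelial microRNAs. Each list's median log2(CPM + 1) was placed among 10000 random lists of the same size drawn from the detected genes and the list's members. Each list's median log2 ratio between the replicates was placed among 10000 random lists in which each member was replaced by 1 of the 20 genes nearest in mean CPM, and percentiles below 2.5 or above 97.5 were called outside the central range. Lists with fewer than 3 detected genes had no such ratio. The genes named are the 10 with the largest mean CPM, every measured muscle-enriched gene, the 4 members of each other list with the largest mean CPM of at least 10, and, among genes with a mean of at least 100 CPM past the binomial test, the 3 with the largest ratio in each direction. Hairpins that share any 20 bases with another annotated microRNA hairpin have uncertain counts. This applies to 80 of the 314 detected genes.

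The alternatives were the either-strand counts, hairpin copies summed, minimum counts of 1 and 100, TMM factors or DESeq2 size factors in place of totals, pseudocounts of 0.1 and 10 CPM, all reads as denominator, the muscle list without its most abundant member, and each replicate left out. Removal of a linear trend on hairpin GC content and exclusion of hairpins that share sequence were added after the data were seen.

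The procedures were tested on simulated data. Poisson counts were drawn for the 314 detected genes at the real means and library sizes, with 200 genes changed in replicate 1 against replicate 2. At a 1.5-fold change the binomial test called 152 of the 200 changed genes and 3 of the 114 unchanged genes, and at a 2-fold change 179 and 6. Simulated coefficients of variation of 0.1, 0.3 and 0.5 were estimated at 0.0977, 0.283 and 0.487. Of 100 simulated lists of 10 genes, 6 fell outside the central range with no shift and 98 with a log2 shift of 1.5. Smaller shifts and shorter lists were not simulated. Of 100 random lists, 5 had a level outside the central 95%. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.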

Results

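MicroRNA sequencing was carried out on myocytes made from C2C12, a mouse myoblast line that was established from injured thigh muscle of the C3H strain and that leaves the cell cycle and forms muscle cells when differentiation is induced. The cells had differentiated for 72 h. The series held 1 group of 2 libraries, which the labels number as biological replicates 1 and 2, so the data answer which microRNAs these myocytes contained and how closely the 2 replicates agreed, and no comparison between conditions was made. Undifferentiated C2C12 cells were not analysed here. Replicate 1 had 15349205 reads, of which 7581366 (49.4%) were assigned to the sense strand of a microRNA gene, and replicate 2 had 18450359 reads, of which 9865298 (53.5%) were assigned. The counts covered 2202 annotated microRNA genes of the mm10 genome build, each a whole hairpin precursor whose 5p and 3p arms were not separated. At least 10 counts in each library were found for 314 genes, which together held 99.98% of the assigned counts in each library. A mean of at least 100 CPM (counts scaled to 1000000 assigned counts per library) was reached by 133 of these genes and a mean of at least 1000 CPM by 65. No count was seen in either library for 1494 genes.

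Mir206, a microRNA restricted to skeletal muscle, had the most assigned counts of any microRNA gene and took 37.9% ± 5.37 of them (SD, n = 2). It made up 34.1% of replicate 1 (2584038 counts) and 41.7% of replicate 2 (4111798 counts). Mir206 (ENSMUSG00000065559.1) lies on the plus strand of chromosome 1 from 20679010 to 20679082, in an exon of the long noncoding RNA gene Gm28653. Mir133b, the other microRNA of that transcript (20682769 to 20682887), was far less abundant, with 12089 ± 2151 CPM and rank 12. The Mir206 count was 25.04 times the Mir133b count in replicate 1 and 39.4 times in replicate 2. Mir133b shares at least 20 bases with the Mir133a genes, so its count and both ratios are uncertain. The 10 most abundant microRNA genes together took 73.7% of the counts in replicate 1 and 78.6% in replicate 2 (76.2% ± 3.48). Reads that fit more than 1 place, 3378438 in replicate 1 and 3295854 in replicate 2, were assigned to no gene. MicroRNAs with several genomic copies can therefore be missing from this ranking or stand too low in it.

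Behind Mir206, the ranking was led by Mir378a with 11.3% ± 3.60 of the counts, Mir21a with 6.09% ± 3.03, Mir22 with 5.45% ± 0.949 and Mir143 with 3.56% ± 1.53 (SD, n = 2 for each). Mir378a (ENSMUSG00000105200.1; chromosome 18, 61397835 to 61397900) lies in an intron of Ppargc1b, the gene of a transcriptional coactivator of mitochondrial metabolism. Mir21a (chromosome 11, 86584067 to 86584158) overlaps an exon of Vmp1, and Mir22 (chromosome 11, 75463716 to 75463810) lies in an exon of its host transcript Mir22hg. The next ranks were held by Mir99a with 2.86% ± 0.126, Mir23a with 2.66% ± 0.363, Mirlet7b with 2.30% ± 0.627, Mirlet7i with 2.05% ± 0.997 and Mir322 with 2.03% ± 1.03. Mir378a shares a stretch of at least 20 bases with Mir378c, and Mir23a shares one with Mir23b, so the counts of these hairpins are uncertain. The spread between replicates was wide enough that the order of Mir21a and Mir22 was not the same in both libraries: Mir21a had 82317 CPM in replicate 1 and 39501 in replicate 2, and Mir22 had 47786 and 61207.

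The list of muscle-enriched microRNAs took 39.2% ± 5.16 of the assigned counts (SD, n = 2), with 35.5% in replicate 1 and 42.8% in replicate 2. Nearly all of these assigned counts came from Mir206: without it the list took 1.30% ± 0.211. Over all reads of a library, unmapped and multi-mapped reads included, the share was 20.2% ± 3.78. Reads that fit more than 1 place were assigned to no gene. The Mir1a and Mir133a genes, Mir133b and Mir486 share sequence with other hairpins, so the part of the list other than Mir206 is uncertain. Of 12 measured members 9 were detected and 4 had a mean of at least 100 CPM. Mir499, encoded in an intron of the myosin heavy chain gene Myh7b, had 471 ± 131 CPM, and Mir208b, in an intron of the slow myosin heavy chain gene Myh7, had 378 ± 166 CPM. Mir208a, in an intron of the cardiac myosin heavy chain gene Myh6, was rarer, with 10.3 ± 4.50 CPM. Mir486, in an intron of the ankyrin gene Ank1, had 30.9 ± 0.294 CPM. It is overlapped on the other strand by Mir3107, with which it shares sequence, so its count is uncertain.

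**Figure D1:**
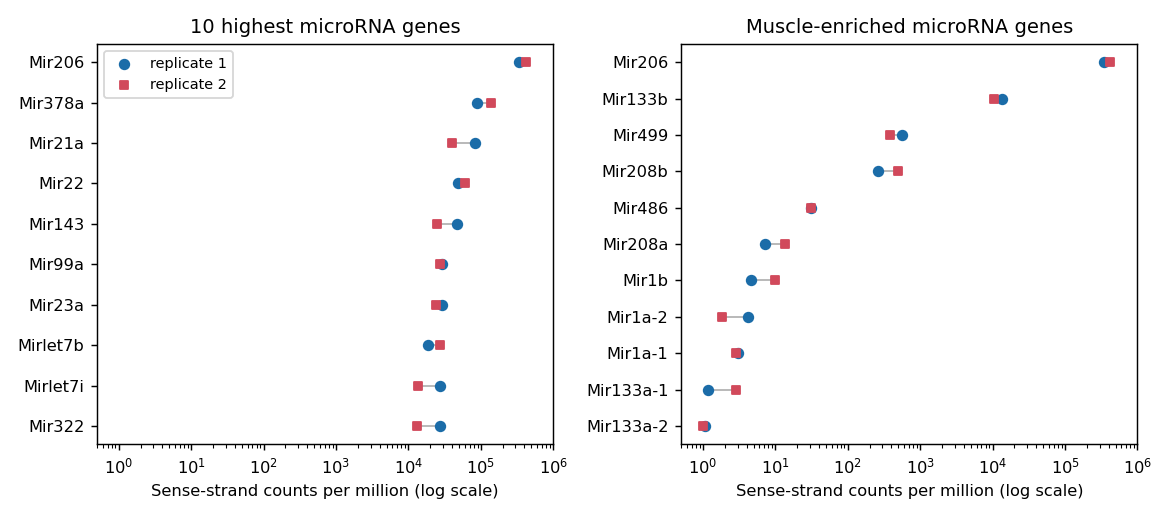
CPM of the 10 most abundant microRNA genes (left) and of the muscle-enriched list (right) on a log axis, with 1 point per replicate and a line joining the replicates; Mir133c, without a count, is not drawn. Mir206 has 340841 and 416794 CPM in the replicates, and the muscle-enriched genes range from there to about 1 CPM.

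The genes of miR-1 and miR-133a, which like miR-206 belong to the classical muscle microRNAs, had few counts. Mir1a-1 had 23 counts in replicate 1 and 28 in replicate 2, and Mir1a-2 had 32 and 18. Mir1b, on the strand opposite Mir1a-2, had 35 and 96 counts. Mir133a-1 had 9 and 28 counts and Mir133a-2 had 8 and 10, so that neither met the minimum of 10 counts in both libraries. Mir1a-1 and Mir1a-2 share sequence with each other, as do Mir133a-1 and Mir133a-2, and reads that map to more than 1 place were assigned to no gene. The levels of miR-1a and miR-133a are therefore uncertain, and the counts given are of uniquely mapped reads alone. Mir133c had 0 counts in both libraries, which allows up to 0.396 CPM in replicate 1 and 0.304 CPM in replicate 2 (3 counts, a one-sided 95% limit).

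The 12 lists of microRNAs were compared by their level within these libraries, as the percentile of the list's median log2(CPM + 1) among 10000 random lists of the same size. Widely expressed microRNAs that have been tied to myoblast differentiation stood high, with a mean percentile of 98.7 ± 0.711 and 16.6% ± 2.65 of the counts (SD, n = 2). All 20 of their measured genes were detected. Beside Mir378a and Mir322 they included Mir351, an X-linked neighbour of Mir322, with 8764 ± 2417 CPM, and Mir27b with 7874 ± 1086 CPM, whose count is uncertain because it shares sequence with Mir27a. Mesenchymal and fibroblast microRNAs stood at percentile 99.7 ± 0.138 and took 16.1% ± 3.92 of the counts. Of their 11 measured genes 10 were detected, led by Mir21a, Mir22 and Mir143, with Mir34c at 4214 ± 4124 CPM. Mir214 belongs to both of these lists.

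MicroRNAs described as higher in proliferating myoblasts were also well represented: 6 of 8 were detected, each at a mean of 100 CPM or more. The list stood at percentile 93.3 ± 1.00 with 1.06% ± 0.745 of the counts (1.59% in replicate 1 and 0.533% in replicate 2). Mir31 had 5419 ± 5545 CPM, Mir221 2905 ± 1429, Mir125b-1 1038 ± 143 and Mir222 469 ± 45.0. Mir125b-1 shares sequence with Mir125b-2, so its count is uncertain. The let-7 family, whose members rise as cells differentiate, had all 12 genes detected, a percentile of 90.7 ± 10.4 and 5.11% ± 0.829 of the counts. After Mirlet7b and Mirlet7i its most abundant genes were Mirlet7g with 2945 ± 2438 CPM and Mirlet7d with 2240 ± 827 CPM. The miR-17-92 cluster and its paralogous clusters, tied to cell cycling, had 11 of 15 genes detected, a percentile of 31.0 ± 21.2 (16.0 in replicate 1, 46.0 in replicate 2, and a mean of 81.2 with hairpin copies summed) and 1.10% ± 0.391 of the counts. They were led by Mir17 with 5138 ± 2102 CPM, Mir93 with 2251 ± 324, Mir106b with 1695 ± 579 and Mir18 with 747 ± 320. The muscle-enriched list, in spite of Mir206, stood at percentile 8.44 ± 8.00 (2.78 in replicate 1 and 14.1 in replicate 2), since most of its members had low counts. This position depended on how hairpin copies and strands were counted: with copies summed the percentile was 23.2, and in the either-strand counts it was 0.04.

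MicroRNAs of other cell types had low levels among the uniquely mapped counts. Blood cell microRNAs stood at percentile 1.27 ± 1.63 with 0.0380% ± 0.00106 of the counts. Mir342 had 231 ± 44.0 CPM and Mir142 had 133 ± 62.6 CPM. Liver and endothelial microRNAs stood at percentile 4.95 ± 5.05 (21.3 with copies summed) with 0.0247% ± 0.0121 of the counts. Among them were Mir126a of the endothelial gene Egfl7 with 130 ± 123.2 CPM (217 in replicate 1 and 42.9 in replicate 2), Mir192 with 102 ± 12.6 CPM and Mir194-2 with 12.5 ± 9.70 CPM. The count of Mir194-2 is uncertain because it shares sequence with Mir194-1. Neural microRNAs had 8 of 16 genes detected and 0.0260% ± 0.000608 of the counts, led by Mir128-1 with 101 ± 6.84 CPM and Mir128-2 with 56.6 ± 6.87, followed by Mir138-1 with 30.9 ± 15.3 and Mir138-2 with 29.3 ± 1.86. These Mir128 and Mir138 copies share sequence, so their counts are uncertain. Fewer than 3 of the detected neural genes share no sequence with another hairpin, so the low share of the neural list is uncertain too. Epithelial microRNAs had 82 counts in replicate 1 and 81 in replicate 2, with 2 of 8 genes detected. None of 14 measured genes of the pluripotent stem cell list was detected, and the list had 6 and 4 counts in all. The imprinted Dlk1-Dio3 cluster was nearly without counts as well, with 10 counts in replicate 1 and 6 in replicate 2 over 49 measured genes. The neural, epithelial, pluripotent and Dlk1-Dio3 lists had a percentile of 0 in both libraries, which means that none of the random lists had a lower median. With copies summed the neural list stood at 3.50. Random lists were drawn mostly from detected genes, whereas these lists kept their undetected members. A percentile near 0 was therefore largely set by the numbers of undetected genes and adds little to them. To a lesser degree this holds for the other lists with undetected members.

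The replicates were closely related across genes and still differed gene by gene by more than counting error. Over the 314 detected genes, log2(CPM + 1) of the libraries had a Pearson r of 0.976 (bootstrap interval over genes 0.969 to 0.982) and a Spearman rho of 0.970. Genes are not independent replicates, and no p is given. The median absolute log2 ratio was 0.51, and 245 genes (78.0%) lay within 2-fold of each other in the replicates. Of the rest, 50 were more than 2-fold higher in replicate 1 and 19 in replicate 2, with library totals as scaling. The biological coefficient of variation estimated by edgeR was 0.420 (bootstrap interval 0.378 to 0.453). The counts differed by more than repeated sampling of the same library gives (chi-square 780465 with 313 degrees of freedom), which does not separate cultures from preparations. The labels give each biological replicate its own biosample and do not state whether the cultures were differentiated separately, so the SDs and this coefficient measure the spread between these libraries, which can be technical in part.

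**Figure D2:**
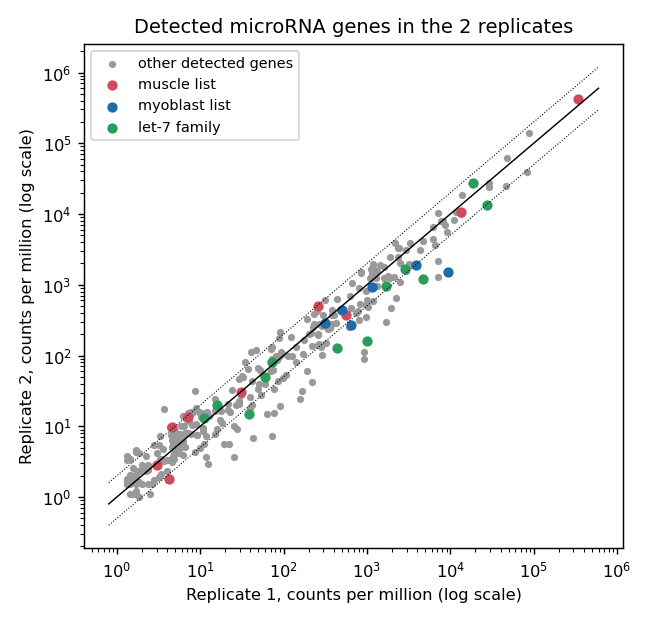
CPM of each of the 314 detected microRNA genes in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, with 3 lists coloured; the solid line marks equal CPM and the dotted lines a 2-fold difference. Within 2-fold lie 245 genes, and 50 lie below the lower dotted line, with more than 2-fold higher CPM in replicate 1.

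By an exact two-sided binomial test with Benjamini-Hochberg adjustment, 209 of 314 genes had an adjusted p below 0.05. With library totals as scaling, 120 of them were higher in replicate 1 and 89 higher in replicate 2. The lean toward replicate 1 was smaller under other scalings, with 109 and 99 genes for TMM factors and 110 and 99 for DESeq2 size factors. With totals and a minimum of 100 counts, the numbers were 104 and 62. The binomial test compares these libraries, not conditions. Among genes with a mean of at least 100 CPM, the largest ratios toward replicate 1 were those of Mir107, Mir20a and Mir31. Mir107, in an intron of the pantothenate kinase gene Pank1, had 911 CPM in replicate 1 and 88.8 in replicate 2 (10.3-fold), although it shares sequence with the Mir103 genes. Mir20a, of the miR-17-92 host transcript Mir17hg, had 923 and 114 CPM (8.11-fold). Mir31 had 9340 and 1498 CPM (6.24-fold). Toward replicate 2 the largest ratios were smaller. Mir33, in an intron of the sterol regulator gene Srebf2, had 90.2 CPM in replicate 1 and 218 in replicate 2 (2.41-fold). Mir142 had 89.0 and 178 CPM (1.99-fold), and Mir152, in an intron of Copz2, had 313 and 600 CPM (1.92-fold). Among the named genes that did not pass the test were Mir486 (adjusted p = 0.920 in the exact binomial test), Mir1a-1 (0.917), Mir138-2 (0.399) and Mir128-1 (0.0690).

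The median ratio between the replicates was compared for the 9 lists with at least 3 detected genes, and none lay beyond the central 95% of 10000 random lists matched on mean CPM. That range reached 1.12 for the 6 myoblast genes and 1.13 for the 4 liver and endothelial genes, so smaller shifts of these lists could pass unseen. The let-7 genes came closest to the edge, with a median log2 ratio of 0.78 (replicate 1 over replicate 2) at percentile 97.4. In this family 8 of 12 genes were higher in replicate 1. Mirlet7g had 4669 CPM in replicate 1 and 1221 in replicate 2, whereas Mirlet7b went the other way with 18538 and 27399. Over 8 alternatives the let-7 median ranged from 0.45 in the either-strand counts (percentile 84.9) to 0.91 without hairpins that share sequence (percentile 95.7), and it lay outside the central range in 2 of the 8. All 6 detected genes of the myoblast list were higher in replicate 1 (median log2 ratio 0.67, percentile 88.9; 1.05 at percentile 95.4 with copies summed and 1.16 at percentile 94.0 without hairpins that share sequence). The muscle-enriched list had a median of 0.02 at percentile 38.4, with 5 genes higher in replicate 1 and 4 in replicate 2. Its sign depended on the processing. The median stayed at 0.02 with minimums of 1 and 100 counts and was −0.08 with TMM scaling and −0.07 with DESeq2 size factors. It was −0.18 (percentile 22.15) in the either-strand counts, −0.29 (percentile 9.8) with copies summed and −0.35 (percentile 12.8) without the GC trend. Mir206 and Mir208b were 1.22-fold and 1.90-fold higher in replicate 2, and Mir133b and Mir499 were 1.29-fold and 1.49-fold higher in replicate 1. Without the genes that share 20 bases with another hairpin, a choice made after the values were seen, 5 muscle genes remained and their median was −0.92 at percentile 0.1. That median was the value of Mir208a, which had 54 and 133 counts. The other lists had medians of 0.13 (differentiation-associated, percentile 40.6), 0.29 (miR-17-92, 57.5), 0.24 (mesenchymal, 53.5), 0.40 (blood, 77.3), 0.33 (neural, 74.3) and 0.98 (liver and endothelial, 96.2). These medians moved with the processing while staying inside the central range. Over the alternatives they ranged from −0.06 to 0.45 for differentiation-associated, 0.17 to 0.71 for miR-17-92, 0.10 to 0.36 for mesenchymal, 0.13 to 0.41 for blood, 0.13 to 0.46 for neural and 0.19 to 0.92 for liver and endothelial microRNAs.

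**Figure D3:**
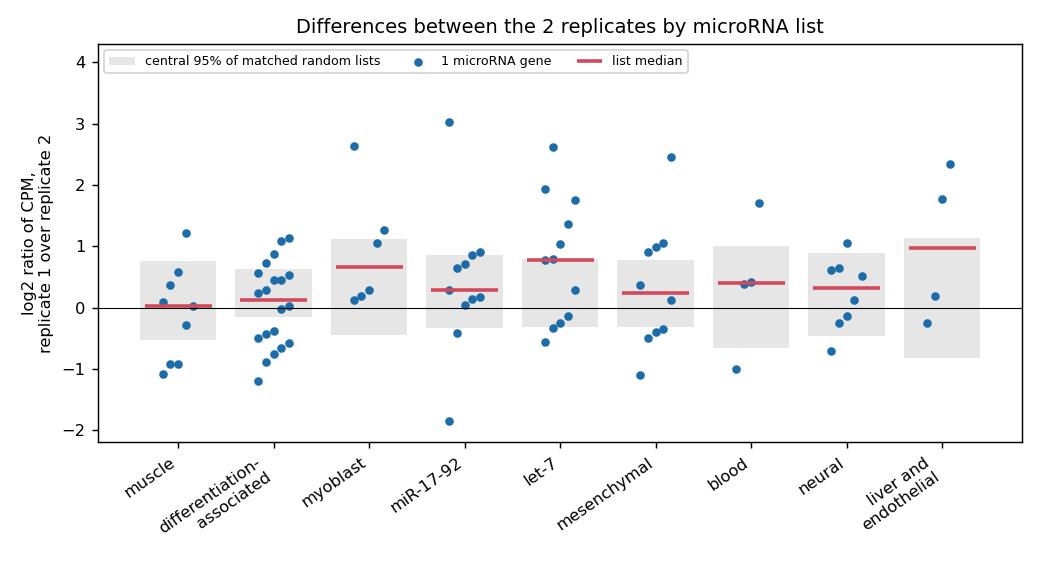
Log2 ratio of CPM in replicate 1 over replicate 2 for the detected genes of 9 lists (points), with the list median (red line) and the central 95% of medians of matched random lists (grey). The medians lie inside the grey range for all 9 lists, and the let-7 median of 0.78 lies closest to its edge of 0.79.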

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

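The test of hairpins that share sequence was chosen only after the counts of Mir1a and Mir133a had been seen. The results of this part are signals in reads that enter no gene level, set against the 3 counts that a count of 0 allows.

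Multi-mapped reads numbered 3378438 in replicate 1 and 3295854 in replicate 2. Reads that mapped uniquely but to the sense strand of no microRNA gene numbered 903243 in replicate 1 and 1027420 in replicate 2. These include reads on the opposite strand of microRNA genes that have no microRNA gene across from them, 75 in replicate 1 and 93 in replicate 2.

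The multi-mapped reads bear on the low counts of microRNAs with several genomic copies. The 4 genes Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 held 72 counts in replicate 1 and 84 in replicate 2, against 2584038 and 4111798 for Mir206. A candidate explanation is that most of their reads fit more than 1 copy and were left out of the gene counts. Over detected genes, the 80 hairpins that share 20 bases with another hairpin had a median of 40.3 CPM and the other 234 a median of 57.6 CPM, a difference of −0.52 on the log2 scale (two-sided permutation test, p = 0.556). This comparison decides nothing, since loss of reads would itself keep genes below the minimum of 10 counts, as it could for Mir133a-1 and Mir133a-2, and as the sequences of the multi-mapped reads were not used here, loss of reads and low expression cannot be told apart; no biological explanation was tested.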

How the results depend on the processing

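The alternatives without hairpins that share sequence and without the GC trend were chosen after the data were seen. Of 114 values under settings fixed earlier, 98 were scored as unchanged, as were 15 of 17 added values. No list lay outside the central range in the main setting, so there was no call on a list to reverse. Of the values scored as changed, 1 under settings fixed earlier and 2 added ones took a list outside that range. The rule differed by result. Median ratios of lists had to stay on their side of the threshold. Shares had to stay within 1 SD of the main value, and list levels within 1 SD or 1 percentile point, whichever was larger. Correlation and dispersion had to stay inside the bootstrap interval. Numbers of genes only had to stay within a fixed fold range, whatever the number tested. Among the 114 values, TMM factors and DESeq2 size factors cannot move a list's percentile between the replicates, since they shift every gene alike. The number of detected genes followed the minimum, with 555 genes at 1 count and 187 at 100, and the correlation was 0.984 and 0.956 at these minimums. With 2 replicates, each lies within 1 SD of their mean by construction, so leaving out a replicate is no test of stability. It gave 331 to 354 detected genes, a muscle share of 35.5% to 42.8% and a share of the 10 highest genes of 73.7% to 79.2%, and percentiles of 2.78 to 14.1 for the muscle list, 16.0 to 46.0 for miR-17-92, 83.4 to 98.1 for let-7, 0.11 to 2.42 for blood and 1.38 to 8.53 for liver and endothelial microRNAs. The muscle share was 44.9% in the either-strand counts, which lack Mir378a and other genes with an opposite neighbour. It was 20.2% of all reads and 1.30% without Mir206. List levels depended on the counting of copies and strands. In the either-strand counts the muscle list moved to percentile 0.04 and the differentiation-associated list to 92.9. With copies summed, the percentiles were 23.2 for muscle, 100 for differentiation-associated, 91.2 for myoblast, 81.2 for miR-17-92, 3.50 for neural and 21.3 for liver and endothelial microRNAs. Between the replicates, the let-7 median was 0.79 (percentile 97.8) at a minimum of 100 counts and 0.70 (percentile 98.4) without the GC trend, but it was inside the central range in its 6 other alternatives, with 0.45 (percentile 84.9) in the either-strand counts. The muscle median was −0.92 (percentile 0.1) without hairpins that share sequence and inside the range in the 7 others. The remaining lists stayed inside the range in every alternative that gave a ratio, although their medians moved (−0.06 to 0.45 for differentiation-associated and 0.51 to 1.16 for myoblast microRNAs, for example). The causes were not tested. Blood and liver and endothelial microRNAs had fewer than 3 genes in the either-strand counts and at a minimum of 100 counts, as had neural microRNAs without hairpins that share sequence, and gave no ratio there. The number of genes that differed between libraries ranged from 166 of 187 tested at a minimum of 100 counts to 227 of 555 at a minimum of 1. It was 209 of 314 in the main setting, so the share of tested genes depended strongly on the minimum. Depth limits genes near 10 counts, and 2 libraries limit every SD.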

Other observations

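The abundant genes of the next paragraphs and the cluster and family pairs were chosen after their values were seen, and so were the tests of sampling depth, GC content, clusters, families and the Dlk1-Dio3 region. The percentile of the muscle list was planned.

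Beyond the lists and the 10 most abundant genes, 36 microRNA genes had a mean of at least 1000 CPM. The most abundant were Mir130a with 16402 ± 3465 CPM (SD, n = 2), Mir23b (which shares sequence with Mir23a) with 11582 ± 2402, Mir99b with 11168 ± 902, and Mir140, which overlaps an exon of Wwp2, with 9746 ± 1990. The 3 genes of the Spaca6 locus on chromosome 17, Mir99b, Mirlet7e and Mir125a, had unequal levels: Mirlet7e had 1324 ± 502 CPM and Mir125a 1307 ± 241. Mir100, a relative of Mir99a and Mir99b on chromosome 9, had 8104 ± 43.7 CPM. The miR-30 family was represented by Mir30a with 6354 ± 331, Mir30d with 3741 ± 897, Mir30e with 2835 ± 604 and Mir30b with 1568 ± 450 CPM.

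A group of microRNAs in introns of the chloride channel gene Clcn5 on the X chromosome was also abundant. Mir532 had 7253 ± 2492 CPM, Mir188 4419 ± 401, Mir500 1312 ± 88.7, Mir501 1181 ± 101 and Mir362 1143 ± 433. The cluster of Mir182, Mir96 and Mir183 on chromosome 6, best known from sensory organs, had 3624 ± 464, 664 ± 435 and 558 ± 115 CPM. Mir335, in an intron of the imprinted gene Mest, had 4636 ± 3506 CPM. Mir210, induced by low oxygen in many cell types, had 2400 ± 68.1 CPM.

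The log2 ratios between the replicates had an SD of 0.91 over the 314 detected genes. For 121 genes with at least 1000 counts in each library the SD was 0.82, against 0.0289 from Poisson sampling, which argues against sampling depth as the cause. Ratios fell with hairpin GC content (Spearman rho −0.28 across detected genes and −0.38 across the 121 genes). Removing a linear trend over detected genes left an SD of 0.88, or 0.962 of the original (bootstrap interval 0.928 to 0.987). This argues against a linear trend on hairpin GC content as the whole cause. The GC content of the sequenced arms was not examined. A different extent of differentiation stays open. The muscle list stood at percentile 38.4 and the myoblast list at 88.9, neither outside the central range. Without hairpins that share sequence the muscle median was −0.92 (percentile 0.1), but that was the value of Mir208a, which had 54 and 133 counts. Of the other genes left, Mir1b (35 and 96 counts) had −1.08 and Mir208b −0.93, whereas the more abundant Mir206 had −0.29 and Mir499 0.57. The libraries may also differ in preparation, which was not tested.

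Among genes with a mean of at least 100 CPM, some within 10 kb of each other on the same strand diverged between the replicates and others did not. In the miR-17-92 cluster the log2 ratio was 3.02 for Mir20a, 0.86 for Mir17, 0.90 for Mir18 and 0.05 for Mir92-1, which shares sequence with Mir92-2. Mir34c had 2.46 and its neighbour Mir34b 0.12, Mir143 had 0.91 and Mir145a −0.39, and Mir322 had 1.08 and Mir351 −0.57. Other neighbours had similar ratios, with 1.48 and 1.67 for Mir15b and Mir16-2, 0.59 and 0.49 for Mir30b and Mir30d, −0.07 and −0.16 for Mir191 and Mir425, and −0.14 and −0.17 for Mir500 and Mir501. Over 53 pairs in 20 clusters, the mean absolute difference in log2 ratio was 0.85 (bootstrap interval 0.65 to 1.06), against 0.94 for shuffled genes (one-sided permutation test, p = 0.167). Transcription of whole clusters alone would give neighbours similar ratios, so these values argue against it as the only source of the spread. The interval leaves room for a part of the spread from such transcription.

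Families were taken as genes with the same number in their symbol (Mir98 counted with let-7) and a mean of at least 100 CPM. Of family members at different loci, Mir34a and Mir34c had log2 ratios of 2.05 and 2.46, and Mir15a and Mir15b had 1.80 and 1.48. Mir34b, of the same family as Mir34a, had 0.12, Mir101b and Mir101a had 0.54 and −0.87, and Mirlet7g and Mirlet7b had 1.93 and −0.56. Over 45 pairs in 15 families, the mean absolute difference was 0.93, against 1.11 for shuffled genes (one-sided permutation test, p = 0.0820). Leaving out the let-7 family, 25 pairs had 0.67 against 1.04 (one-sided permutation test, p = 0.00374). A hypothesis from these values is that part of the spread may depend on the microRNA sequence, through library preparation or through the stability of the mature microRNA. The test over all families does not decide it, and the better result without let-7 rests on a choice made on the same data. Grouping by number also left related genes with other numbers unpaired, such as Mir99a and Mir100, so these were not full sequence families.

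The near absence of the Dlk1-Dio3 microRNAs covered a large cluster. Between its outermost listed genes on chromosome 12 (109563692 to 109743795) the annotation has 64 microRNA genes, which held 10 counts in replicate 1 and 6 in replicate 2, whereas 9 detected genes elsewhere on the chromosome held 8246 and 10853. Of the 49 listed members, 42 share no 20 bases with another annotated microRNA hairpin, and these held 8 and 5 counts. For these members, this argues against sequence shared between annotated hairpins as the cause. Sequence shared with other places in the genome was not examined. The median detected gene had 399 counts in the library with the lower median, and the highest member of the cluster had 4. This comparison cannot decide on a lack of depth, since detected genes were chosen for at least 10 counts in each library. No listed member reached that minimum, so the order was fixed by the choice. A hypothesis is that the cluster may be silent in these cells, and no biological explanation was tested.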
